A study of Mus musculus with 107 samples.

How the data were processed

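Liver RNA of female F2 mice from C57BL/6J and DBA/2J parents, fed an atherogenic diet, was measured on 2-colour arrays, each mouse against a common pool. The values deposited by the authors are read here as log10 ratios of mouse to pool, 1 value per probe and array. The labels give neither the log base nor the direction, and dyes and normalization are not given in the sources used here. The base was taken as 10 because values stop at exactly -2 and +2, which is 100-fold under that base. Array medians lay near 0, so the arrays had been brought to a common centre before deposition or measured so.

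The choice of base departed from the rule set before the data were examined. That rule took the base and direction for which the mean ratio over mice, in the 200 probes of largest SD, lay nearest 0 on the log scale. Over 104 arrays it picked base e (-0.0122), before base 2 (-0.0330) and base 10 (0.0730), each for mouse over pool, and over the 86 arrays without the limit-rich ones it picked base 10 (0.0300). Each of these values is a log in its own base, so they are not in a common unit. A log10 unit is 2.30 natural log units. In a common unit base 10 lay farthest from 0 on both sets of arrays for mouse over pool, so this rule gives base 10 no support. The slope of the mean log ratio on its variance was -0.592 over 104 arrays and -1.11 over 86, where a pool of equal parts gives -1.15 for base 10, -0.500 for base e and -0.347 for base 2. A slope on the covariance of 2 probes of a gene, chosen after seeing the data, was -1.25 (95% bootstrap interval -2.03 to -0.801). Under the natural logarithm each fold would be smaller, while correlations, ranks and likelihood ratios would stay the same.

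The design named 107 mice. Arrays of 3 mice held only 0 or missing values and were left out, which leaves 104. Further choices were made after seeing the data. Values at -2 or +2 (12821 and 13265 values, 1.07% of all) were treated as not measured. A further 1.69% of values were missing. Arrays with over 700 values at the limits were treated as a technical batch of 18, and the other 86 were analysed alone beside all 104. The mouse numbers of the 18 run from 59 to 107, a range that also holds 13 other arrays. The median array had an SD over probes of 0.43 log2 (range 0.24 to 1.41). No array was repeated, so array noise and differences between mice were not separated, and signal over background was not analysed here.

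Of 23536 probes, 20633 had values on at least 90% of the 104 arrays. Probes were named through the platform annotation and the gene table of assembly GRCm38.p6. Of all probes, 14744 had 1 symbol, 18 had several and 8774 none here, and probes without a single symbol were left out of gene-level results. The 13238 kept probes with a single symbol gave 12319 genes, of which 11972 were named through the current gene table, and the probes of a gene were averaged. The chromosomes and distances used for neighbours come from the same assembly, since the array annotation names none, and no coordinates are given.

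The spread of a gene was its 5th to 95th percentile range over mice, with a bootstrap interval of the SD (1000 draws). The 36 lists of genes, of pathways, processes and cell types, were fixed before the data were examined, as were the 18 pairs of lists and the tests. Of 491 listed gene entries, 485 matched by symbol, 5 by synonym and 1 not at all. The mean pairwise Pearson r of each list with at least 3 measured genes was compared with 10000 random lists of the same size, matched on SD decile. Each member was correlated with the mean of the other members, each scaled to SD 1. Pairs of list scores were correlated without the genes in both lists. Pearson r and Spearman rho each had 100000 permutations, two-sided, and p-values were adjusted by Benjamini and Hochberg over the lists, the members or the pairs, at a threshold of 0.05.

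The 1:2:1 test compared a mixture of 3 normal distributions with equally spaced means and 1 SD with a single normal distribution, with p from 100000 simulated samples. Called genes with an excess kurtosis below 0 are termed light-tailed, a division made after seeing the data. Neighbours were pairs of called genes 1 to 20 Mb apart, tested with 10000 permutations of the positions. X-linked genes were compared with autosomal genes for a better fit of a mixture of 2 equal classes. No genotypes were analysed here, and no groups of mice made by the fit were compared. Mice in the outer classes of the fitted mixture were only counted. The tests of 1:2:1 mixtures, neighbours, lists and pairs of lists were tried on simulated data, and those of single list members and X-linked genes were not. Of list pairs with a true r of 0, 4.50% passed an unadjusted threshold of 0.05, and 87.8% did so with a true r of 0.3.

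The text names genes by a rule set in advance: the 12 widest ranges, the 12 largest likelihood ratios, up to 4 members of each list with the largest r and any negative member, 5 sex-linked genes and 7 genes with alleles known to differ between the parents, of which 1 is not reported here. The light-tailed genes, their correlated partners and the intestinal genes were chosen after their values were seen.

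Alternatives set in advance were subtraction of array medians, probes measured on every array, the probe of largest SD per gene, removal of the first principal component from every gene, odd or even mice alone, leaving out the 5 arrays of widest spread or the 2 mice farthest from the median, Spearman in place of Pearson, random lists not matched on SD, shared genes kept, SD times 3.29 as the range, free means, a 1:3 mixture, distances of 1 to 10 or 1 to 50 Mb, and all placed genes. Alternatives chosen after seeing the data were values at the limits kept, leaving out the limit-rich arrays, those arrays alone, the light-tailed genes alone as neighbours, and leaving out the 3 mice of the most extreme score of each list. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.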

Results

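The data were liver expression profiles of female F2 mice from a cross of the inbred strains C57BL/6J and DBA/2J, fed an atherogenic diet, which raises blood lipids. In an F2 generation each mouse carries its own mixture of the 2 parental genomes. Each mouse's liver RNA was hybridised on a 2-colour array against a common pool that the labels describe as equal RNA portions of all the mice. The labels state 111 mice. Of the 107 arrays analysed here, 3 held only 0 or missing values, for mice 24, 55 and 91, so n = 104 mice of 1 group. There were no treated and control groups to compare. The question the design allowed was how far genes and gene groups differed from mouse to mouse, which of them varied together, and which followed the pattern of a single segregating locus. No array was repeated on the same RNA, so the spread over mice includes array noise, and the number of arrays limits the precision.

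Each array gave 23536 probe values as log10 ratios, of which 20633 probes had a value on at least 90% of the 104 arrays. Array medians lay between -0.09 and 0.07 on the log2 scale. The median array had 452.5 probes more than 2-fold from the pool, with a range of 118 to 4108. A batch of 18 arrays, with mouse numbers from 59 to 107, held 946 to 1828 values at the limits of the scale, against 0 to 496 on the other 86 arrays. These are called limit-rich arrays, and values are given with and without them. The correlation between 2 arrays over all probes had a median of 0.133, a highest value of 0.686 and a lowest value of -0.463.

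The direction of the ratios was not settled, because no dye was named in the sources used here and 7 of 5356 pairs of arrays correlated below -0.3. Those pairs involved 10 arrays. Mouse over pool was the likely direction, from the order of the sample titles and from the mean ratio over mice, which lay nearest to that of an equal mixture under it. With all signs turned, each median and percentile changes sign and high and low mice change places. Ranges, SDs, correlations and likelihood ratios stay as they are. The correlation of an array with the median of the others had a lowest value of -0.0543 and a median of 0.361, with 1 array below 0, and this is where a single turned array would show. Over the 53 probes with a median under -0.4 on the log10 scale, at least 83.3% lay below the pool on each array.

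**Figure D1:**
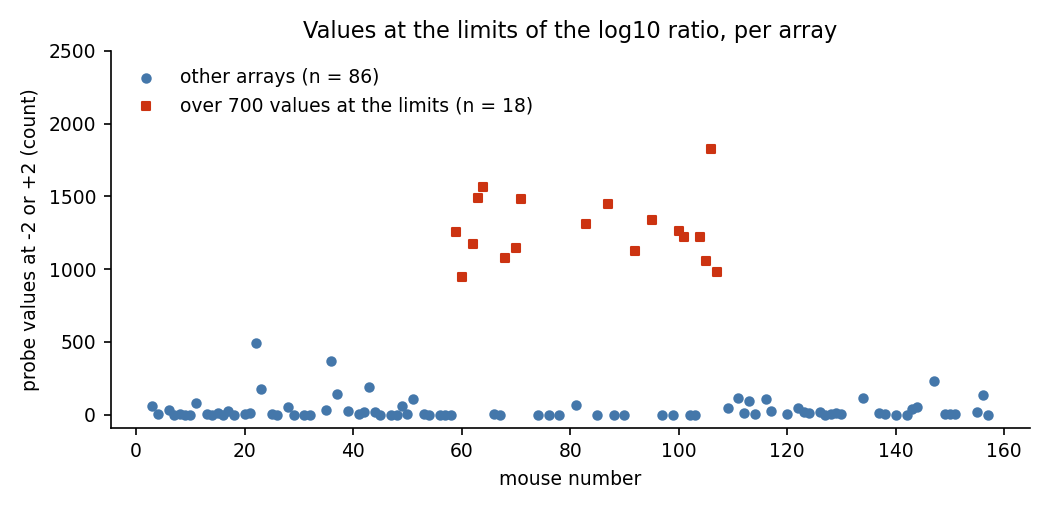
Number of probe values at the limits of -2 and +2 on the log10 scale (vertical axis, count) for each of the 104 arrays by mouse number (horizontal axis). Squares are the 18 limit-rich arrays, with 946 or more such values, and circles the other 86 arrays, with 496 or fewer.

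The 12 genes of widest range over mice were of several kinds, and no test for a shared role was made. Each was measured by 1 probe here, so no second probe backs these ranges. Sult3a1, a sulfotransferase more abundant in female than in male mouse liver, had the widest range, 211-fold between the 5th and 95th percentiles (SD 2.73 log2, 95% bootstrap interval 2.39 to 3.00, n = 102 mice). Pdxdc1 followed with 170-fold (SD 2.83, interval 2.51 to 3.03, n = 102) and Mmp7, a matrix metalloproteinase of epithelia, with 137-fold (SD 2.06, interval 1.71 to 2.33, n = 104). The 5th percentiles of Sult3a1 (-6.17 log2) and Pdxdc1 (-6.14) lay near the lower limit of the scale, -6.64 log2. Values at that limit were treated as not measured, so it may bound both ranges. Sema3e ranged over 91.7-fold (SD 1.93 log2, n = 100) and Ngp, a neutrophil granule protein, over 64.8-fold (SD 1.81, n = 104). Cyp4a14, a fatty acid hydroxylase, ranged over 59.5-fold (SD 1.58), Hao2, a peroxisomal oxidase, over 55.0-fold (SD 1.79), and Sult1e1, the estrogen sulfotransferase, over 51.5-fold (SD 1.87). Car3 ranged over 47.4-fold (SD 1.93, n = 102), Acta1, skeletal muscle actin, over 46.0-fold (SD 1.68, n = 98), Dmbt1 over 44.4-fold (SD 1.60) and Ces3a over 43.1-fold (SD 1.49).

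Of 12319 genes, 5778 (46.9%) had a range above 2-fold, 1112 above 4-fold and 173 above 10-fold. The median range was 1.94-fold. The Y-linked genes Eif2s3y and Kdm5d, which female mice lack, also exceeded 2-fold, at 2.38-fold and 2.87-fold (1.58-fold and 2.10-fold without the limit-rich arrays). A range above 2-fold alone therefore does not show that expression of a gene differed between mice. Without the limit-rich arrays 4719 genes exceeded 2-fold, 4546 of them among the 5778, and 100 exceeded 10-fold. Among the 12 widest genes, the range of Ngp was then 28.0-fold and that of Acta1 23.0-fold. Folds assume a base of 10, and would be smaller under base e or 2. Pairs of probes of the same gene correlated over mice with a median r of 0.188 (859 genes with at least 2 probes), so much of the spread of a single probe was not shared by a second probe of that gene.

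**Figure D2:**
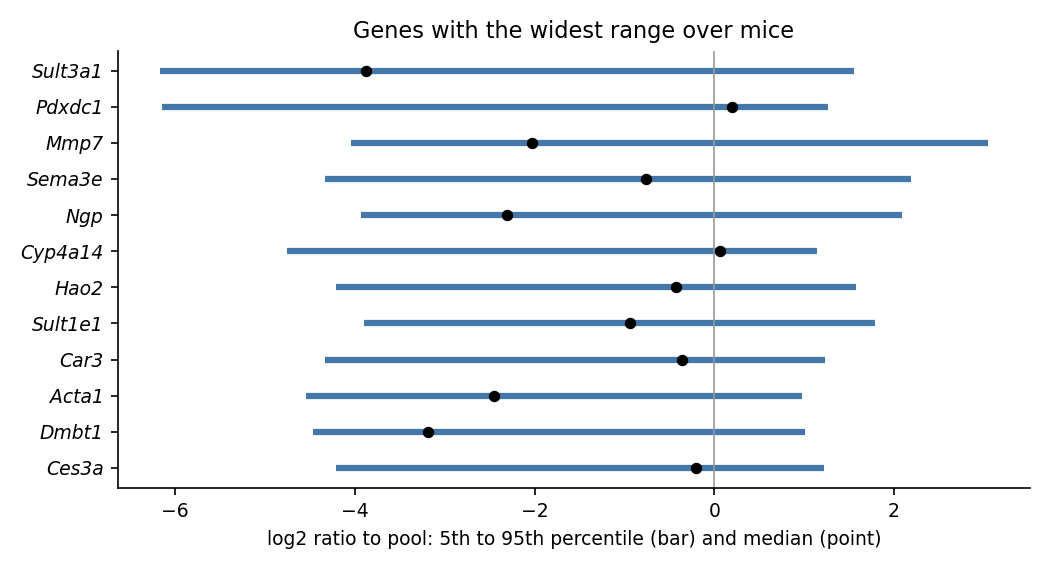
The 12 genes with the widest range over mice. Bars run from the 5th to the 95th percentile of the log2 ratio to the pool (horizontal axis) and points mark the median, with the pool at 0. Sult3a1 spans 7.72 log2 units.

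Most lists of genes with a known shared role varied together more than random genes of the same spread. The random lists were not matched on gene family, chromosome or signal level. Scores of lists with different roles were also often correlated: of 578 pairs not fixed in advance, 149 passed as positive and 110 as negative. Variation together was therefore not particular to the role of a list. Some lists hold several genes of the same family, such as the Cyp2c, Cyp2d, Cyp3a and Orm genes, whose probes may share signal. Shared probe signal and linkage were not separated from a shared role. Of 35 lists with at least 3 measured genes, 31 had a mean pairwise correlation above that of random lists at an adjusted p under 0.05. Of 356 list members tested, 307 correlated positively with the rest of their list, 5 negatively, and 44 did not pass. Adjusted over the list alone, the counts were 307 and 4, Abcg1 being the member lost. By rank, 281 of the 312 called members passed with the same sign, and 309 kept their sign without the 2 mice farthest from the median. Random lists had a median correlation near 0, and the smallest p they could give was 1e-04 (1.67e-04 after adjustment over the 35 lists). For single members the smallest possible permutation p was 1e-05, adjusted 1.53e-05 for r and 1.66e-05 for rho over all 356 members. Values for lists are mean pairwise r over the 104 mice, then over the 86 arrays and over the 18 limit-rich arrays.

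**Figure D3:**
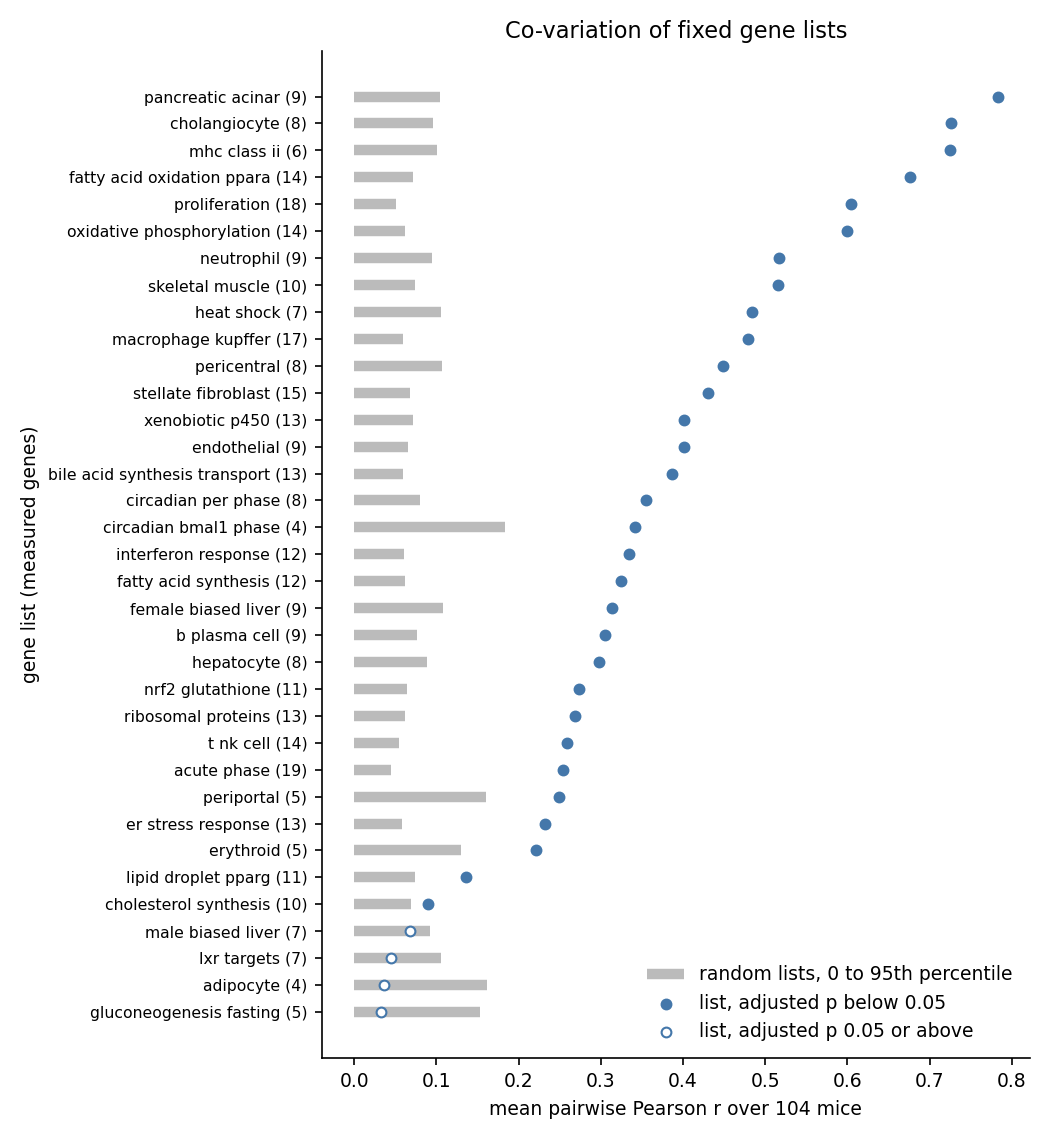
Mean pairwise Pearson r over 104 mice (horizontal axis) of each of 35 gene lists, with the number of measured genes in brackets. Grey bars reach the 95th percentile of 10000 random lists of the same size and spread, filled points mark an adjusted p below 0.05 and open points one of 0.05 or above. The 9 pancreatic acinar genes lie highest, at 0.783.

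Genes of fatty acid oxidation, many of them targets of the nuclear receptor PPAR alpha, formed the most coherent metabolic list, at 0.676 (0.687 and 0.655, adjusted p = 1.67e-04), and all 14 members were positive. Cpt2, of mitochondrial import, had r = 0.954 with the rest of the list (rho = 0.939), Acot1 r = 0.933 (rho = 0.935), Ehhadh r = 0.928 (rho = 0.888) and Cyp4a10 r = 0.924 (rho = 0.902). Cyp4a10 ranged over 23.8-fold and Acot1 over 17.6-fold. Fatty acid synthesis reached 0.325 (0.343 and 0.181, adjusted p = 2.92e-04), with 11 of 12 members positive. The desaturases Fads1 (r = 0.781, rho = 0.722) and Fads2 (r = 0.694, rho = 0.636) and the regulator Mlxipl (r = 0.716, rho = 0.628) led it, with Pklr next. Lipid droplet genes gave 0.136 (0.171 and 0.0541, adjusted p = 0.0105), with 8 positive members of 11. Cidec (r = 0.580, rho = 0.569) and Plin2 (r = 0.577, rho = 0.557) led these, followed by Mogat1 and Cd36, and Fabp4 was negative (r = -0.202, adjusted p = 0.0462, rho = -0.165, adjusted p = 0.110).

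Cholesterol synthesis was only weakly coherent at 0.0902 (0.0575 and 0.187, adjusted p = 0.0253), with 7 of 10 members positive and Sc5d negative (r = -0.373, rho = -0.235). Msmo1 had r = 0.411 but rho = 0.0848, and Idi1 r = 0.374 but rho = 0.0142. Insig1 and Mvd followed, and neither passed by rank. This call rested on few mice: without the 3 mice of the most extreme score the value was -0.00941 (adjusted p = 0.578), and without the limit-rich arrays its adjusted p was 0.111. LXR targets, which include exporters of cholesterol and regulators of lipid synthesis, reached 0.0454 (adjusted p = 0.192) and did not pass. In that list Abcg8 (r = 0.576, rho = 0.402), Abcg5 and Srebf1 were positive and Abcg1 negative (r = -0.213, rho = -0.252), while the receptor Nr1h3 passed as negative by rank alone (r = -0.0180, rho = -0.326, adjusted p = 0.00124). Genes of gluconeogenesis and fasting gave 0.0323 (adjusted p = 0.312), with G6pc (r = 0.411, rho = 0.383) the 1 positive member of 5, while Ppargc1a, Pck1 and Fbp1 did not pass.

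Bile acid synthesis and transport gave 0.387 (0.405 and 0.292, adjusted p = 1.67e-04), with all 13 members positive. Slc27a5 and Baat, which conjugate bile acids, had r = 0.890 (rho = 0.776) and r = 0.812 (rho = 0.608), the bile acid receptor Nr1h4 r = 0.817 (rho = 0.625) and the importer Slc10a1 r = 0.726 (rho = 0.743). Drug-metabolising cytochrome P450 genes gave 0.401 (0.412 and 0.304, adjusted p = 1.67e-04), with 12 of 13 positive. Cyp2d10 (r = 0.878, rho = 0.731), Cyp2c38 (r = 0.845, rho = 0.752) and Cyp2f2 (r = 0.844, rho = 0.712, range 28.6-fold) led, followed by Cyp2e1. Glutathione and Nrf2 genes gave 0.274 (0.262 and 0.300, adjusted p = 2.92e-04), with 10 of 11 positive, led by Ugdh (r = 0.851, rho = 0.815) and Gstm1 (r = 0.746, rho = 0.756), with Gsta2 and Gstm3 next. Female-biased liver genes gave 0.313 (0.318 and 0.281, adjusted p = 5.60e-04), with all 9 positive, among them Cyp2b9 (r = 0.753, rho = 0.717) and Hao2 (r = 0.726, rho = 0.690), then Cyp2b13 and Abcd2. With the first principal component removed from every gene this list lost its call, and Cyp2b13 (-0.0357), Cyp3a41a (-0.251) and Cyp17a1 (-0.158) turned negative. Male-biased genes gave 0.0679 (adjusted p = 0.103) and did not pass, although 4 of 7 members were positive: Cyp7b1 (r = 0.363, rho = 0.342), Hsd3b5, Slco1a1 and Elovl3.

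Genes marking the zones of the liver lobule varied together on both sides. Pericentral genes gave 0.449 (0.447 and 0.483, adjusted p = 1.67e-04), with 7 of 8 positive, led by Glul, glutamine synthetase (r = 0.834, rho = 0.712), and Cyp2e1 (r = 0.757, rho = 0.575), then Lgr5 and Slc1a2. Periportal genes gave 0.249 (0.258 and 0.0945, adjusted p = 0.0176), with 4 of 5 positive, led by the urea cycle enzyme Ass1 (r = 0.548, rho = 0.506), then Hal, Arg1 and Cyp2f2. General hepatocyte genes gave 0.298 (0.314 and 0.160, adjusted p = 6.73e-04), with 7 of 8 positive, led by Apoa1 (r = 0.741, rho = 0.732), then Arg1, Ahsg and Apoc3. On the 18 limit-rich arrays alone the periportal and lipid droplet lists missed the threshold, with adjusted p of 0.191 and 0.137, as did periportal genes with probes measured on every array and lipid droplet genes in even-numbered mice.

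Inflammatory and immune genes formed several coherent groups. Acute phase genes, many of which encode proteins secreted by hepatocytes in inflammation, gave 0.254 (0.271 and 0.149, adjusted p = 1.67e-04), with 16 of 19 positive, led by Orm1 (r = 0.829, rho = 0.759) and Orm2 (r = 0.757, rho = 0.744, range 10.5-fold), then Steap4 and Lbp. Class II antigen presentation genes gave 0.724 (0.751 and 0.605, adjusted p = 1.67e-04), with all 6 positive, H2-DMb1 at r = 0.931 (rho = 0.937) and H2-Ab1 at r = 0.928 (rho = 0.939), followed by Cd74 and H2-Aa. Interferon response genes gave 0.334 (0.334 and 0.448, adjusted p = 1.67e-04), with 10 of 12 positive, led by Ifit3 (r = 0.810, rho = 0.807), Ifit1, Irgm1 and Irf7. Macrophage and Kupffer cell genes gave 0.480 (0.478 and 0.513, adjusted p = 1.67e-04), with 15 of 17 positive, C1qc at r = 0.951 (rho = 0.949) and C1qb at r = 0.943 (rho = 0.939), then Tyrobp and Fcer1g. Trem2 was negative (r = -0.314, rho = -0.367), with an SD of only 0.16 log2. Clec4f, also of this list, had a negative r that did not pass, and gave 0.525 with the first principal component removed. Neutrophil genes gave 0.517 (0.503 and 0.592, adjusted p = 1.67e-04), with 8 of 9 positive, Ngp at r = 0.915 (rho = 0.853) then Camp, S100a9 and S100a8, the last ranging over 38.5-fold. T and NK cell genes gave 0.259 (0.318 and 0.122, adjusted p = 1.67e-04), with 12 of 14 positive, led by Cd2 (r = 0.861, rho = 0.659), Cd3g, Ccl5 and Il2rb. Cd4 was negative by r (-0.230) but did not pass by rank (rho = -0.0870). B and plasma cell genes gave 0.304 (0.307 and 0.216, adjusted p = 1.67e-04), with 8 of 9 positive, led by Mzb1 (r = 0.760, rho = 0.694), Cd79b, Pou2af1 and Ms4a1. Without the 3 mice of the most extreme score, T and NK cell genes fell to 0.113 and acute phase genes to 0.163, both still past the threshold.

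Structural cell types also stood out. Stellate cell and fibroblast genes gave 0.430 (0.452 and 0.450, adjusted p = 1.67e-04), with 14 of 15 positive, among them the collagens Col1a2 (r = 0.910, rho = 0.914) and Col1a1 (r = 0.908, rho = 0.914, range 41.2-fold), with Sparc and Col4a1 between and after them. Cholangiocyte genes, of the bile duct epithelium, gave 0.726 (0.735 and 0.796, adjusted p = 1.67e-04), with all 8 positive, led by Cldn7 (r = 0.943, rho = 0.799) and Krt7 (r = 0.906, rho = 0.798), then Cftr and Epcam. Endothelial genes gave 0.401 (0.444 and 0.0796, adjusted p = 1.67e-04), with 8 of 9 positive, led by Kdr (r = 0.790, rho = 0.772), Eng, Tek and Pecam1, and missed the threshold on the 18 limit-rich arrays (adjusted p = 0.129). Erythroid genes gave 0.221 (0.237 and 0.292, adjusted p = 0.0106), with 4 of 5 positive, led by Slc4a1 (r = 0.455, rho = 0.428), Epb42, Alas2 and Hba-a1, but lost its call with probes measured on every array and with values at the limits kept. Adipocyte genes gave 0.0365 (adjusted p = 0.309), and Lipe, Slc2a4, Retn and Adipoq did not pass by r, Lipe alone by rank (rho = 0.202, adjusted p = 0.0492).

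Genes of 2 other tissues varied in a few mice. Pancreatic acinar genes, which encode digestive enzymes, gave 0.783 (0.795 and 0.859, adjusted p = 1.67e-04), with all 9 positive. Cpa1 (r = 0.942, rho = 0.686) led them, then Prss2, a trypsin, Ctrl and Cela2a, but mice 76, 100 and 140 had scores far above the others. Without those 3 mice the list gave 0.327 (adjusted p = 2.50e-04). Skeletal muscle genes gave 0.516 (0.591 and 0.0261, adjusted p = 1.67e-04), with 9 of 10 positive, led by Tnni2 (r = 0.898, rho = 0.293), Ckm, Tnnc2 and Myh4. Without the 3 extreme mice the value was 0.160 (adjusted p = 0.00204), and on the 18 limit-rich arrays the adjusted p was 0.274.

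Clock genes split into 2 groups, each varying together. The group that peaks with Arntl, the gene also called Bmal1, gave 0.341 (0.458 and 0.326, adjusted p = 0.00907), with 3 of 4 positive, Clock at r = 0.711 (rho = 0.715) and Arntl at r = 0.668 (rho = 0.712), then Nfil3, while Npas2 passed by rank alone (r = 0.117, rho = 0.340). The group that peaks with the Per genes gave 0.355 (0.382 and 0.347, adjusted p = 2.92e-04), with 7 of 8 positive, Usp2 at r = 0.815 (rho = 0.822) and Dbp at r = 0.811 (rho = 0.843, range 16.3-fold), then Tef and Per2. Proliferation genes gave 0.604 (0.686 and 0.431, adjusted p = 1.67e-04), with all 18 positive, Top2a at r = 0.913 (rho = 0.795), then Cdk1, Ccna2 and Cdc20. Oxidative phosphorylation genes gave 0.600 (0.610 and 0.599, adjusted p = 1.67e-04), with 13 of 14 positive, Atp5c1 at r = 0.883 (rho = 0.871), then Uqcrc2, Ndufv1 and Cox6c, although only 5 of them ranged above 2-fold. Heat shock genes gave 0.484 (0.493 and 0.517, adjusted p = 1.67e-04), with all 7 positive, Hsph1 at r = 0.846 (rho = 0.863), then Hspa8, Hsp90aa1 and Dnajb1. Genes of endoplasmic reticulum stress gave 0.232 (0.229 and 0.235, adjusted p = 1.67e-04), with 10 of 13 positive, Creld2 at r = 0.827 (rho = 0.754), then Hspa5, Sdf2l1 and Calr. Ribosomal protein genes gave 0.268 (0.289 and 0.109, adjusted p = 1.67e-04), with 12 of 13 positive, Rps3 at r = 0.766 (rho = 0.618), then Rpl7, Rplp0 and Rpl3, and 0.174 without the 3 extreme mice.

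Mice with high macrophage gene scores had high collagen and other stellate cell scores and low P450 scores. Of 18 pairs of lists fixed in advance, 17 could be tested, and 10 passed, 8 positive and 2 negative. Macrophage and stellate scores correlated with r = 0.759 (p = 1e-05, adjusted 2.43e-05, rho = 0.753, p = 1e-05, adjusted 1.70e-05). The value was 0.736 without the 2 mice farthest from the median, 0.758 on the 86 arrays and 0.809 on the 18. Macrophage and P450 scores gave r = -0.516 (p = 1e-05, adjusted 2.43e-05, rho = -0.626, p = 1e-05), -0.482 without 2 mice, -0.521 on the 86 arrays and -0.540 on the 18. With the first principal component, 16.7% of the variance, removed from every gene this relation turned to 0.253 and passed in that direction (adjusted p = 0.0243). Macrophage and acute phase scores gave r = 0.531 (p = 1e-05, adjusted 2.43e-05, rho = 0.628, p = 1e-05), 0.544 without 2 mice, 0.505 on the 86 arrays and 0.679 on the 18. Proliferation and macrophage scores gave r = 0.384 (p = 3e-05, adjusted 6.37e-05, rho = 0.568, p = 1e-05), 0.495 without 2 mice, 0.321 on the 86 arrays and 0.684 on the 18, and -0.159 with the first component removed. Neutrophil and acute phase scores gave r = 0.249 (p = 0.0136, adjusted 0.0232, rho = 0.474, p = 1e-05), 0.443 without 2 mice and 0.530 on the 18 arrays, but 0.175 on the 86 arrays, where the adjusted p was 0.168. That pair also missed the threshold in even-numbered mice (0.128, adjusted p = 0.428) and without the 5 widest arrays (0.224, adjusted p = 0.0513).

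Fatty acid synthesis varied with fatty acid oxidation, r = 0.645 (p = 1e-05, adjusted 2.43e-05, rho = 0.560, p = 1e-05), with 0.543 without 2 mice, 0.637 on the 86 arrays and 0.785 on the 18. With the first component removed it was 0.00197. Lipid droplet genes varied with fatty acid oxidation, r = 0.491 (p = 1e-05, adjusted 2.43e-05, rho = 0.459, p = 1e-05), with 0.412 without 2 mice, 0.506 on the 86 arrays and 0.450 on the 18 (adjusted p = 0.119). Female-biased and male-biased scores rose together, r = 0.508 (p = 1e-05, adjusted 2.43e-05, rho = 0.487, p = 1e-05), with 0.485 without 2 mice, 0.509 on the 86 arrays and 0.543 on the 18, and turned to -0.140 with the first component removed. Periportal and pericentral scores also rose together, r = 0.376 (p = 1.10e-04, adjusted 2.08e-04, rho = 0.246, p = 0.0123), with 0.317 without 2 mice, 0.390 on the 86 arrays and 0.327 on the 18 (adjusted p = 0.253), and gave -0.0209 with the first component removed. The Arntl and Per groups of clock genes, which peak at opposite times of day, ran against each other, r = -0.673 (p = 1e-05, adjusted 2.43e-05, rho = -0.700, p = 1e-05), with -0.637 without 2 mice, -0.647 on the 86 arrays and -0.722 on the 18. The smallest permutation p possible was 1e-05.

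The other 7 pairs did not pass. Cholesterol synthesis gave r = 0.0762 with fatty acid synthesis (p = 0.434, adjusted 0.527, rho = 0.00709, p = 0.943), and -0.0597 without 2 mice. That pair passed with probes measured on every array (0.229, adjusted p = 0.0336) and with the first component removed (0.220, adjusted p = 0.0483). Cholesterol synthesis gave r = -0.118 with bile acid genes (p = 0.213, adjusted 0.279, rho = -0.104, p = 0.292), but passed without 2 mice (-0.214, adjusted p = 0.0453) and in even-numbered mice (-0.382, adjusted p = 0.0112). With acute phase genes it gave r = -0.0521 (p = 0.570, adjusted 0.646, rho = -0.0270, p = 0.785), and -0.0516 without 2 mice. Fatty acid synthesis and lipid droplet scores gave r = 0.00138 (p = 0.989, adjusted 0.991, rho = -0.0399, p = 0.688), and -0.126 without 2 mice, but passed with the first component removed (-0.311, adjusted p = 0.00417). Acute phase and P450 scores gave r = 0.00102 (p = 0.991, adjusted 0.991) but rho = -0.393 (p = 1e-05, adjusted 1.70e-05). It was -0.104 without 2 mice, and 0.236 (adjusted p = 0.0324) with the first component removed. Interferon and class II genes gave r = 0.179 (p = 0.0703, adjusted 0.109, rho = 0.160, p = 0.107), with 0.252 on the 86 arrays (adjusted p = 0.0330) and -0.170 on the 18. That pair also passed without 2 mice (0.234, adjusted p = 0.0280) and with the first component removed (0.371, adjusted p = 3.40e-04). Adipocyte and lipid droplet scores gave r = 0.158 (p = 0.110, adjusted 0.156, rho = 0.0900, p = 0.364), and 0.0843 without 2 mice. Female-biased genes with major urinary proteins could not be tested, because the major urinary protein list had under 3 measured genes. Of 578 other pairs of lists, adjusted among themselves, 149 were positive and 110 negative.

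**Figure D4:**
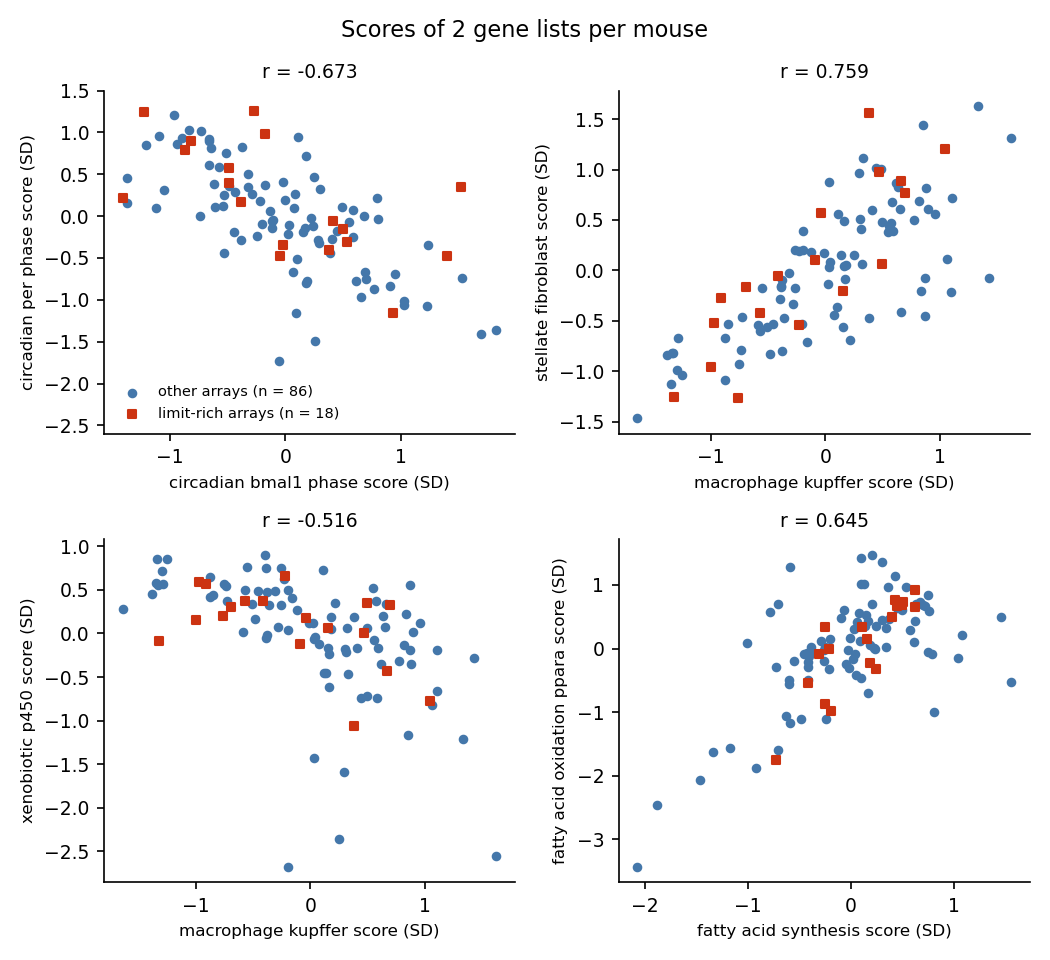
Scores of pairs of gene lists, each point a mouse and each axis the mean of the list's genes scaled to SD 1. Circles are the other 86 arrays and squares the 18 limit-rich arrays, and r over all 104 mice is above each panel: -0.673 for the Arntl and Per clock groups, 0.759 for macrophage and stellate genes, -0.516 for macrophage and P450 genes, 0.645 for fatty acid synthesis and oxidation.

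A gene ruled by 1 autosomal locus in an F2 cross should fall into 3 levels in the ratio 1:2:1. At an adjusted p under 0.05, 92 genes fitted such a mixture better than a single normal distribution, against 273 at an unadjusted p under 0.05, which is fewer than the 616 of 12319 that chance would give if each gene followed a single normal distribution. Of the 92, 8 had light tails, as 3 separate levels give: Stk25, Ogg1, Crym, Ehd1, Zfp949, Ocel1, Rrs1 and Ifi202b. Crym, a thyroid hormone binding protein, had fitted levels 2.70-fold apart (likelihood ratio 29.6, adjusted p = 0.00176) and a range of 7.86-fold. Ogg1, a DNA repair glycosylase, had levels 1.52-fold apart (likelihood ratio 30.4, adjusted p = 0.00176), Stk25, a kinase, 1.60-fold (30.6, adjusted p = 0.00176) and Ehd1 1.38-fold (27.2, adjusted p = 0.00176). Zfp949 had levels 2.27-fold apart (23.4, adjusted p = 0.00176), Ocel1 1.56-fold (20.3, adjusted p = 0.00176), Rrs1 1.69-fold (17.0, adjusted p = 0.00986) and Ifi202b, an interferon-inducible gene, 2.49-fold (13.6, adjusted p = 0.0420). Without the limit-rich arrays 18 genes were called, 10 of them among the 92, and 4 of the light-tailed genes passed: Crym, Ehd1, Ogg1 and Stk25. Light-tailed calls numbered 15 with the first component removed, 6 of them among the 8, 9 with array medians subtracted (7 among the 8), and 6 without the 5 widest arrays (6 among the 8). They numbered 29 with values at the limits kept (8 among the 8), 120 with free means (8 among the 8) and 154 with a 1:3 mixture (6 among the 8).

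The other 84 called genes had heavy tails, including the 12 of largest likelihood ratio: Sycn, Dpp6, Gnao1, Zfp59, Olfr938, Chrne, E130201H02Rik, Slc7a13, Drd2, Mcpt9, Zbtb3 and 4930521O11Rik. Sycn, a pancreatic granule protein, had the largest ratio, 112, with an excess kurtosis of 29.3. In simulated data the test called 0% of genes whose levels lay 1 or 2 within-level SDs apart, 36% at 3 and 98% at 4 (50 genes each among 12319), so most loci of small effect would be missed. It also called 6 of 12119 simulated normal genes and 20 of 12319 simulated heavy-tailed genes without levels, 0 of the latter with light tails. Genes simulated with heavy tails all but fix that 0 in advance, so it does not bear on the light-tailed calls. How many of the 6 normal genes had light tails was not counted. The simulated genes were also drawn independently of each other.

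**Figure D5:**
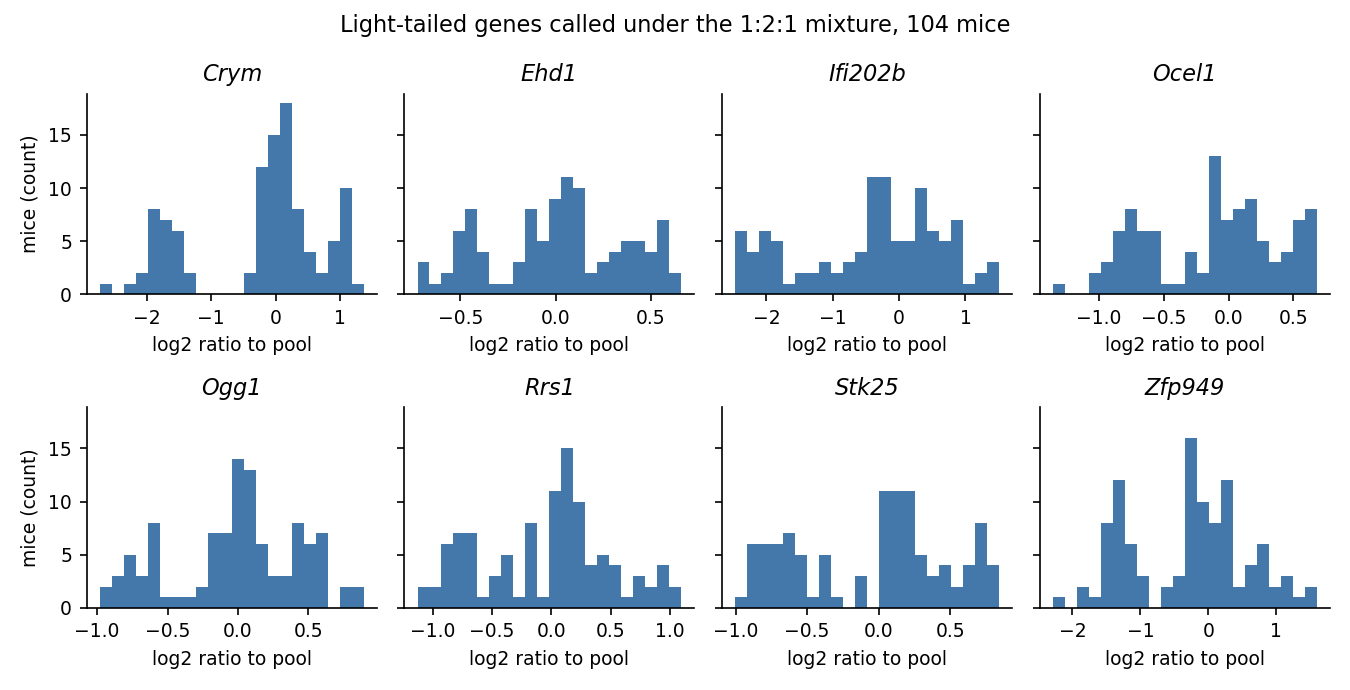
Number of mice (vertical axis) by log2 ratio to the pool (horizontal axis) for the 8 light-tailed genes called under the 1:2:1 mixture, 104 mice each. Crym shows a group of mice below -1 apart from the others.

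Genes on the same chromosome share genotypes in an F2, so called genes near each other could vary together. Over 88 called genes with a place in GRCm38.p6, 69 pairs lay 1 to 20 Mb apart and had a mean absolute r of 0.182, against 0.168 for 3569 pairs on different chromosomes, a difference of 0.0139 (one-sided permutation p = 0.227). Without the limit-rich arrays, with 18 genes and 5 pairs, the difference was 0.484 (p = 0.0363), and without the 5 widest arrays, with 44 genes and 13 pairs, 0.134 (p = 0.00810). For the X chromosome, 1 gene was called under either mixture, too few for a comparison. It was not fitted better by 2 equal classes, against 18 of 104 autosomal genes (two-sided Fisher's exact test p = 1).

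Genes with alleles known to differ between C57BL/6J and DBA/2J varied over mice without passing the mixture test. Gpnmb, a melanosome protein that DBA/2J carries in a truncated form, ranged over 38.0-fold (SD 1.71 log2, likelihood ratio 8.70, adjusted p = 0.391). Hc, complement component C5, ranged over 6.00-fold, Glo1 over 3.76-fold, Alad over 3.37-fold and Nnt over 2.75-fold, each with an adjusted p of 1. Xist, expressed from the inactive X chromosome, ranged over 2.24-fold (SD 0.37). The Y-linked genes Eif2s3y and Kdm5d, which female mice lack, ranged over 2.38-fold and 2.87-fold. The range of Nnt thus did not exceed that of Kdm5d over the 104 mice. Without the limit-rich arrays the 2 ranges were 2.67-fold and 2.10-fold. Ddx3y, Uty and H2-Ea had no probe with enough values.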

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

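The limit-rich arrays, the values at the limits, the 3 mice of the most extreme score and the light-tailed genes alone were tests chosen after the data were seen, and the other settings were set in advance. Per setting, genes above 2-fold numbered 4033 to 6973 against 5778, coherent lists 27 to 32 against 31, and relations past the threshold 8 to 12 against 10. Of the other values, 439 of 455 for lists, 2372 of 2458 for list members and 200 of 221 for relations kept direction and side of the threshold, and 31 of 306 ranges of named genes moved, 18 of them on the limit-rich arrays alone. With the first component removed 10 relations passed, but only 5 of the 10 reported did so with the same sign. Macrophage with P450 passed with the opposite sign (0.253, adjusted p = 0.0243). Lists that lost their call were cholesterol synthesis, periportal and erythroid genes with probes measured on every array, cholesterol synthesis and lipid droplets in even mice, female-biased genes with the first component removed, erythroid genes with values at the limits kept, cholesterol synthesis by rank and without the limit-rich arrays, and lipid droplet, periportal, endothelial and muscle genes on those arrays alone. With probes measured on every array, the log mean ratio was 0.0337 (0.0730 reported), the agreement of probes 0.256 (0.188) and genes called 1:2:1 were 20 (92). With values at the limits kept these were 0.782, 0.161 and 1758, and without the limit-rich arrays 0.0300, 0.226 and 18. The 1:2:1 count was 45 without the 5 widest arrays, 2353 with free means and 2627 with a 1:3 mixture. The neighbour difference (0.0139) was 0.134 without the 5 widest arrays and 0.484 without the limit-rich ones, with fewer genes. With the first principal component removed, signs turned for fatty acid synthesis with lipid droplets (-0.311), macrophage with P450 (0.253), female-biased with male-biased (-0.140), periportal with pericentral (-0.0209) and proliferation with macrophage (-0.159). They also turned for members with the rest of their list: Elovl5 (-0.123), Cyp8b1 (-0.275), Cyp7b1 among bile acid genes (-0.0828), Slc10a1 (-0.0103), Igfbp1 (0.432), Fabp4 (0.176), Abcg1 (0.447), Cyp2c40 (-0.0348), Cyp2b13 (-0.0357), Cyp3a41a (-0.251), Cyp17a1 (-0.158), Cyp2f2 among periportal genes (-0.0425), Ttr (-0.314), Clec4f (0.525) and Trem2 (0.0178). Without the 3 mice of the most extreme score the cholesterol synthesis list gave -0.00941 (0.0902 reported). Acute phase with P450 (0.00102) gave -0.319 in odd mice and -0.393 by rank. No pair of light-tailed genes lay 1 to 20 Mb apart, so that setting gave no value. Beyond the number of genes or arrays left, the cause was not tested.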

Other observations

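The tests of the heavy-tailed genes, of the limit-rich arrays for the light-tailed genes and of the chromosome of the light-tailed genes' partners were chosen after the result was seen, and the lists of single mice are values seen in the data. Single mice stood apart in 1 or several lists. Proliferation genes were highest in mouse 20, with a list score of 5.24 against 1.96 in the next mouse, and all 18 genes had their highest value there. The same mouse was high in neutrophil (2.28) and T and NK cell genes (1.95) and low in class II (-2.70), P450 (-2.36), acute phase (-2.11) and hepatocyte genes (-1.69). T and NK cell genes were highest in mouse 26 (4.10), which had the lowest scores of hepatocyte (-2.04), fatty acid oxidation (-3.43), bile acid (-2.98) and P450 genes (-2.68). Cholangiocyte genes were highest in mice 130, 15 and 71 (3.58, 3.20 and 3.12). Pancreatic acinar genes, of digestive enzymes, were highest in mice 76, 100 and 140 (5.19, 5.08 and 4.01, next 0.81), and skeletal muscle genes in mice 44, 23 and 36 (5.52, 3.25 and 2.24).

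In the list scores outside the pairs fixed in advance, bile acid genes varied with P450 genes (r = 0.902, rho = 0.779; 0.861 without 2 mice, 0.916 on the 86 arrays, 0.797 on the 18) and against stellate cell genes (r = -0.660, rho = -0.799; then -0.792, -0.647 and -0.802). Fatty acid oxidation ran against stellate cell genes (r = -0.651, rho = -0.721; then -0.675, -0.628 and -0.764), and female-biased genes against macrophage genes (r = -0.587, rho = -0.694; then -0.650, -0.586 and -0.545). Each had the smallest permutation p possible, 1e-05, for r and rho (adjusted 5.25e-05 and 5.90e-05), and these 4 were picked from 578 such pairs. A probe of the Y-linked gene Eif2s3y that had too few values off the limits lay below the pool on 103 of 103 mice, with a median of -1.40 log2, while the other Eif2s3y probe (-0.01) and Kdm5d (-0.07) lay near it.

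Heavy-tailed genes called under the 1:2:1 mixture may owe their extreme values to the limit-rich arrays. Of 639 values farther than 4 robust SDs from the gene's median, 518, or 81.1%, lay on these arrays, against a median of 68.9% and a highest value of 78.1% in 10000 random sets of genes not called with a like number of such values (p = 1e-04, the smallest possible), so most of this excess is shared by genes not called. Whether a segregating locus plays a part stays open: the sparser outer class held a median of 2 mice, but these genes were picked for heavy tails, which few mice in an outer class give. Without the limit-rich arrays 6 of the 84 heavy-tailed genes were still called. Among them were Sycn and Dpp6, which had the largest likelihood ratios (adjusted p = 0.0088 each, 1:2:1 test). The calls of Sycn and Dpp6 therefore do not rest on the limit-rich arrays. The other named genes of largest likelihood ratio, from Gnao1 to 4930521O11Rik, were not called without those arrays. Why the limit-rich arrays carry extreme values was not tested.

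The 8 light-tailed genes called under the 1:2:1 mixture may follow a locus on their own chromosome. A test set before its result was seen did not show a locus near the gene. Their mean absolute r with genes 1 to 20 Mb away was 0.143, against a median of 0.181 in 10000 random sets (one-sided p = 0.966). A second try with the first component removed gave p = 0.555. Each mean runs over 42 to 261 genes, and a local locus may move only a few of them. Over all placed genes, pairs at that distance hardly differed from pairs on different chromosomes (0.185 against 0.184). By the rule set in advance, a mean at or below the median of random sets counted against a local locus, and 0.143 met that rule. Because so few of the averaged genes may follow such a locus, the test is read here as unable to decide. That reading departs from the rule. Looking instead at the most correlated gene beyond 1 Mb, it lay on the same chromosome for 6 of the 8 genes (at most 5 in random sets, p = 1e-04, the smallest possible): Ocel1 with Zfp930 (r = -0.789, rho = -0.800), Ogg1 with Lrp6 (r = -0.708, rho = -0.697), Crym with Hddc3 (r = 0.703, rho = 0.615), Ifi202b with Apcs (r = 0.694, rho = 0.698), Stk25 with Wdfy1 (r = -0.642, rho = -0.625) and Ehd1 with Pcsk5 (r = 0.630, rho = 0.595), each picked as the strongest of all genes and 4 of them, all but Lrp6 and Hddc3, 1 to 20 Mb from their partner, a count that was not itself tested. In that order, r was -0.775, -0.696, 0.678, 0.691, -0.573 and 0.577 on the 86 arrays and -0.896, -0.829, 0.836, 0.688, -0.875 and 0.828 on the 18, and without 2 mice it kept its sign in each pair. A test set before its value was seen, on 120 other light-tailed genes past the 1:2:1 test only without adjustment, gave 24 such genes, or 20%, against a median of 7.5% and a highest value of 19.2% in random sets (p = 1e-04), so linkage is a hypothesis found and tested on the same mice, with an earlier test that did not show its nearest form and could not decide it, and no genotypes analysed here. A sequence variant under 1 probe was not seen for Stk25, whose 2 probes had r = 0.927 (rho = 0.932, 0.926 without 2 mice, 0.919 on the 86 arrays and 0.982 on the 18). Whether these 2 probes overlap was not analysed here. The other light-tailed genes had 1 probe each, so such a variant could not be tested in them and stays open. Without the limit-rich arrays the 8 genes kept a median of 71.3% of the likelihood ratio (27.0% to 98.7%).

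Most intestinal genes, listed after their medians were seen, lay below the pool: 17 of 25 measured had a median under -1 log2, among them Muc3, S100g, Mep1b, Prap1, Sis and Vil1, with arithmetic mean ratios over mice of 0.084, 0.098, 0.107, 0.139, 0.150 and 0.190. Some others lay near the pool: Fabp6, Mep1a and Guca2a had medians of 0.0233, 0.0159 and -0.025 log2 and mean ratios of 1.03, 1.02 and 0.986. A few measured mice with high levels would raise the pool and the mean together. The median mean ratio over the 25 genes was 0.386, where the mean of an equal mixture is 1. This argues against a few high mice as the only cause. It does not exclude them beside a bias between the labelling channels, which could lower the mean in either case. RNA in the pool from mice without values here stays open, since a channel bias would give genes picked for low medians the same low mean ratio, so the same 0.386 does not tell these apart. In 10 of the 25 genes no mouse lay above the pool, and with the sign turned the median mean ratio, pool over mouse, was 5.96. A bias between the labelling channels stays open too, as no swapped array was analysed here, and no biological explanation was tested.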
